A study of Homo sapiens with 24 samples.

How the data were processed

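Human fetal heart and adult heart RNA, which the labels call commercial polyA RNA in 1 field and total RNA in another, was amplified, labelled with Cy5 or Cy3 and hybridised in pairs to 24 arrays on 3 slides. Per the labels, the authors processed the scans with Agilent's Feature Extraction 7.5 and kept good features alone, so that saturated or outlying features are blank. The deposited values are log10 ratios of red (Cy5) over green (Cy3), by the convention of that software; the labels state neither the log base nor the direction. The lowest value was exactly -2 on this scale, a 100-fold ratio, and arrays with swapped dyes correlated negatively (r from -0.962 to -0.925), so the values had not been turned for the dye swap. Any further normalisation is not given in the sources used here. The values carry steps of 0.01 (0.033 on the log2 scale). The median of the 24 columns over analysed features lay between -0.00494 and 0.00621 on the log10 scale. Of 45312 cells, 2121 (4.68%) were blank, and because saturated features are blank, some of the most abundant transcripts can be missing. No intensities were used, so whether a probe was above background was not known, and the ratios of dim features can understate a difference. Groups were taken from the dyes and RNAs in the labels: 11 arrays with fetal RNA in Cy5, 7 with fetal RNA in Cy3, 3 adult self-self and 3 fetal self-self. Slides 1 and 2 each held 6 fetal against adult arrays with balanced dyes, and slide 3 held 5 arrays with fetal RNA in Cy5 and 1 with fetal RNA in Cy3.

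Features were named through the platform annotation supplied for this table: 1198 of 1888 features had 1 gene symbol, 2 had several and 688 had none and are called unnamed. This match was checked on the 37 genes with 2 tested features, whose ratios differed by a median of 0.219 on the log2 scale against 0.927 for 10000 random pairs of features. For 10 of the 39 genes with several features the features differed in call, and for 0 were they called in opposite directions. In all, 186 unnamed features that behaved like control spots were left out, of which 155 had a self-self median below -0.5 on the log10 scale and 31 were at exactly 0 on 0.5 or more of the arrays. The labels do not mark controls, so this rule was chosen after seeing the data and narrows the fixed design, which tested every probe; the counts with these features kept are among the alternatives. Because the rule reads the self-self ratio, it lowers the self-self background. In addition, 1 feature was left out under a rule fixed beforehand for genes that mark a donor's sex, and other genes of the X chromosome were kept. This left 1701 features.

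Values were converted to log2. The fetal/adult ratio was estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the dye orientation (1 for fetal in Cy5, -1 for fetal in Cy3) and a dye term, on the 18 fetal against adult arrays, for the 1639 features with at least 3 values in each orientation. P-values were adjusted by the Benjamini-Hochberg method, and a call needed an adjusted p below 0.05 and a log2 ratio of at least 1 in size. The same thresholds were used for the mean self-self ratio and for the difference between fetal and adult self-self ratios, on features with at least 2 values for each RNA. For gene lists, limma's cameraPR was run on the moderated statistics of 1123 genes with a preset correlation of 0.01, for the 18 of 24 lists with at least 5 genes tested, and again with an estimated correlation. A gene with several features was represented by the feature with most values. The background of these tests is the genes on this array, which is not a random choice of genes.

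The groups, tests, 24 lists and alternatives were fixed before the data were examined. The named genes were the 12 with the highest and the 12 with the lowest ratio among called features with a symbol that had values on at least 12 of 18 arrays and the same sign on each; in each tested list up to 3 called members with the largest change and the member with the smallest; and, where measured, a set of heart genes (NPPA, NPPB, MYH6, MYH7, MYL4, MYL7, TNNI1, TNNI3, HBG1, HBG2, IGF2, COL1A1, COL3A1 and AFP), of which IGF2 was tested. The part of the rule on dye-biased features named none. A list of 92 kidney genes was written after the largest ratios had been seen. Other genes named in the text (members of small lists, further called members and features without a test) were chosen after their values were seen.

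On simulated ratios with the missing values, dye terms and spread of the 1639 features, the fetal against adult fit called 100% of the features among 200 changed ones that were changed 2.5-fold, 4-fold or 8-fold, 0% of those changed 1.5-fold, which lie under the threshold, and 0 unchanged features. For the self-self difference, 97.4% of features shifted by 1.5 on the log2 scale were called among 1569 features, with 0 others. In 20 simulated runs a shifted list passed the list test in 20, and 2 of 340 tests of other lists passed. The simulated genes were drawn independently, whereas the correlation estimated within the real lists reached 0.467. These list counts therefore do not carry over to correlated lists.

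Alternatives covered centring and scaling of arrays, the minimum number of values, the fold threshold, limma's treat, the dye term, the self-self arrays in the fit, slide as a fixed or random block, slides alone or left out, 1 dye-balanced value per slide, each orientation alone, the row on the slide, robust regression, 1 feature per gene and leaving out each array. Alternatives on the control-like features, on features with a gene symbol and on exact zeros were chosen after seeing the data.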

Results

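Transcript levels in human fetal heart and adult heart were compared on 2-colour oligonucleotide arrays, in which both RNAs are labelled with different fluorescent dyes, Cy5 (red) and Cy3 (green), and hybridised together. The series held 24 arrays on 3 slides of 8. On 11 arrays the fetal RNA carried Cy5 and the adult RNA Cy3, and on 7 arrays the dyes were swapped. The remaining 6 arrays were self-self hybridisations, with the same RNA in both channels (3 with adult and 3 with fetal RNA). The labels name 1 commercial fetal and 1 commercial adult heart RNA and no donors or lots, so the arrays were taken as repeat measurements and n counts arrays, not hearts. The p-values measure only the spread between arrays, and a difference between the RNAs cannot be separated from a difference between the preparations used. Between 1744 and 1845 of the 1888 features had a value on each array. The values are ratios with no intensities beside them, so signal over background was not known. The number of arrays limits the precision. Their scale (log10) and direction (red over green) follow the convention of the scanning software and are not stated in the labels.

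Fetal heart RNA had higher levels of genes of the extracellular matrix and of fetal growth, by list tests with a preset correlation. Both lists also passed with an estimated correlation, which for the growth list was no stricter than the preset. The lists of acute stress genes (higher in fetal), ribosomal proteins and translation factors (higher in fetal) and fatty acid oxidation (higher in adult) passed with the preset correlation alone (adjusted p = 0.14, 0.47 and 0.142 with an estimated correlation). Among genes measured on at least 12 arrays, the highest log2 fetal/adult ratio was that of SPP1, which encodes the secreted phosphoprotein osteopontin, at 4.43 ± 0.018 (SE, n = 18 arrays; limma, adjusted p = 3e-30). It was followed by CDH16, a cadherin known from kidney epithelium, at 3.75 ± 0.019 (n = 16), and by the globin gene HBM at 3.59 ± 0.019 (n = 17). VCAM1 and ICAM1, adhesion molecules that bind leukocytes, stood at 3.22 and 2.97, and the chemokine gene CXCL6 at 3.16 ± 0.11. The other genes among the 12 highest were the protease gene ADAMTS4 (3.05), ANLN (2.96), whose product acts in cytokinesis, IGFBP3 (2.90), FGF13 (2.89), the elastin gene ELN (2.83) and NFKBIA (2.81), which encodes an inhibitor of NF-kappaB. The second ELN feature gave 1.36.

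In the other direction, the lowest ratio among the named genes was that of CHGB, a protein of secretory granules, at -3.33 ± 0.034 (SE, n = 18 arrays; limma, adjusted p = 1.02e-24). THRSP, a regulator of lipid synthesis, stood at -3.13, ADIPOQ, the fat cell hormone adiponectin, at -2.98, and CIDEA, a lipid droplet protein, at -2.76. The coagulation factor gene F5 was at -2.87, and FAM81B at -3.10. MYH2, a fast skeletal myosin heavy chain, was at -2.72, MYOM3, a protein of the sarcomeric M-band, at -2.62, and SLN, which encodes sarcolipin, an inhibitor of the calcium pump of muscle, at -2.24. CCN5 (-2.66), FGF14-AS2 (-2.26) and the transcription factor gene HLF (-2.20) completed the 12.

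**Figure D1:**
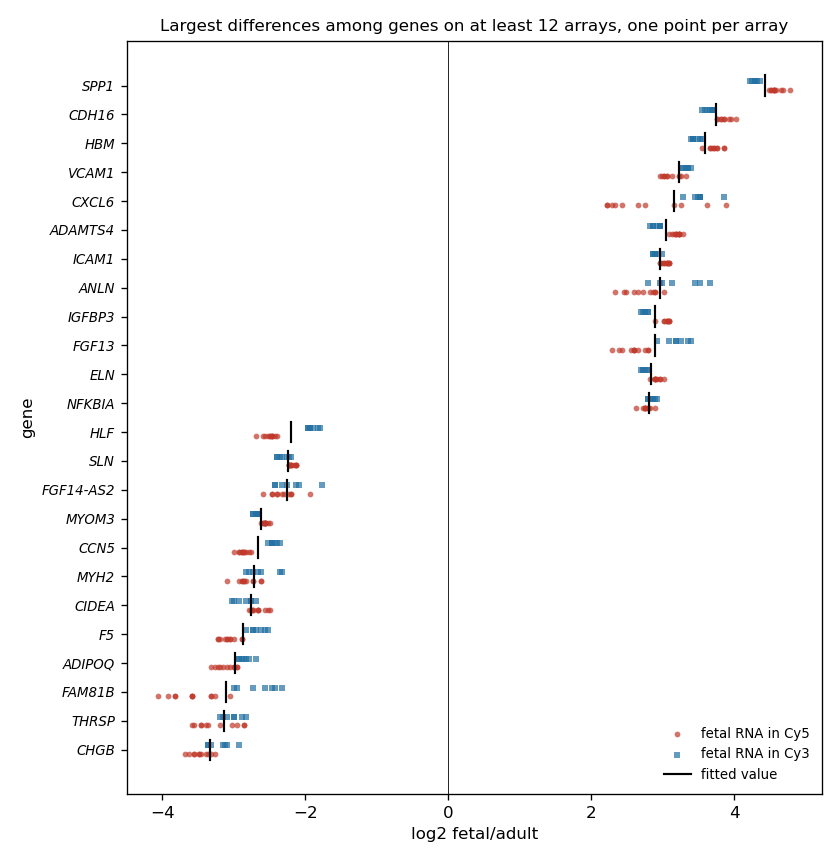
Log2 fetal/adult ratio (horizontal axis) of the 12 genes highest in fetal and the 12 highest in adult heart RNA (vertical axis) among genes with values on at least 12 arrays, with 1 point per array, by the dye of the fetal RNA, and a bar at the fitted value. Every point of the first 12 genes lies above 0 and every point of the others below 0, with CXCL6 among the genes whose points spread most.

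In total, 505 of the 1639 features tested (30.8%) were called at an adjusted p below 0.05 and a difference of at least 2-fold, 304 higher in fetal and 201 higher in adult heart RNA. Of these, 229 and 142 features had 1 gene symbol, and they stood for 225 and 139 genes. How the features of this array were chosen is not given in the sources used here, and a choice by an earlier fetal/adult ratio was not ruled out, so the share applies to this array alone. All 505 had the same sign on every array that measured them. At 4-fold or more, 52 features were higher in fetal and 21 in adult. The adjusted p alone was passed by 1335 features (81.5%) and the median SE was 0.016 on the log2 scale. In a fit that kept the 186 control-like features, 157 of them passed it too. Passing the adjusted p alone therefore does not set a feature apart from these. The dye orientations gave means that correlated across features with Pearson's r = 0.968 and Spearman's rho = 0.916, where features are not independent replicates, and within slides 1, 2 and 3 this r was 0.963, 0.966 and 0.947. With slide as a fixed block 508 features were called, and slides 1, 2 and 3 alone gave 488, 527 and 442. The features of this array were unevenly distributed in their ratio: 637 lay within 0.2 of 0 on the log2 scale, 46 between 0.4 and 0.6, and 135 between 0.6 and 0.8.

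**Figure D2:**
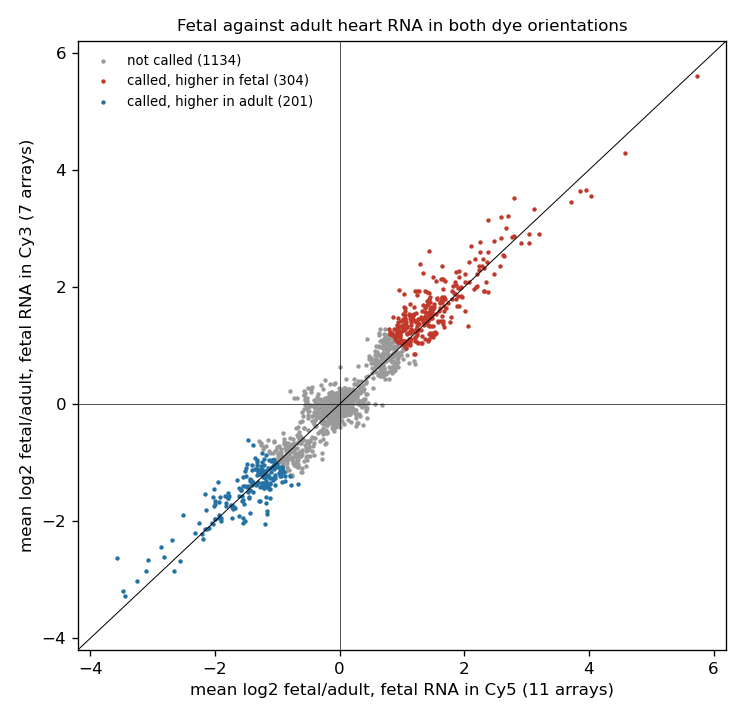
Mean log2 fetal/adult ratio of each of the 1639 features with the fetal RNA in Cy5 (horizontal axis, 11 arrays) against the mean with the fetal RNA in Cy3 (vertical axis, 7 arrays), with the line of equality. The features lie along that line (r = 0.968), with the 304 called higher in fetal in red and the 201 called higher in adult in blue.

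The extracellular matrix and growth genes formed the lists with the lowest p. Of 23 genes of collagens and extracellular matrix, 15 were higher in fetal and 1 in adult heart RNA, and 7 were not called. ADAMTS4 stood at 3.05, COL5A1, a fibrillar collagen chain, at 2.15 ± 0.012 (SE, n = 17 arrays) and COL12A1 at 2.11. TIMP4, an inhibitor of matrix metalloproteinases, was the member higher in adult, at -1.32, and MMP9 was at -0.02. Of 6 fetal and imprinted growth genes, 4 were higher in fetal, among them IGFBP3 (2.90), the growth factor IGF2 (2.06 ± 0.012, n = 11 arrays) and the RNA-binding protein IGF2BP1 (2.03), and CDKN1C, at 0.56, was not called. Both lists were shifted towards fetal by limma's cameraPR, with an adjusted p of 3.02e-05 and 0.0013 over 18 lists. With an estimated correlation (0.0661) the matrix list held (cameraPR, adjusted p = 0.00609). For the growth list the estimate was negative (-0.0395) and was taken as no correlation. This is laxer than the preset 0.01, so its rerun (cameraPR, adjusted p = 0.00178) was no stricter check. The median log2 ratio of the matrix list was 1.28, 1.37 and 1.24 on slides 1, 2 and 3, and that of the growth list 1.78, 1.90 and 1.68. With slide as a block the adjusted p was 5.51e-05 and 0.000922. Beside them, of 10 measured genes on a list of kidney markers, 9 were called higher in fetal, but the list was written after the largest ratios had been seen, 7 of the 10 had been seen high, and enrichment was not tested. The 3 not seen before were ENPEP (1.53), ELF3 (1.41) and MME (0.05, not called).

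The list of acute stress genes leaned to fetal heart RNA, with an adjusted p of 0.00202 with the preset correlation and adjusted p = 0.14 with an estimated correlation. Of 8 immediate early, heat shock and stress genes, 6 were higher in fetal and 1, the small heat shock protein gene HSPB7 (-1.17), in adult. CXCL8, the neutrophil chemokine interleukin-8, had the largest ratio of all features, 5.67 ± 0.033 (SE), but had values on 7 arrays (3 and 4 by orientation). The transcription factor ATF3 was at 2.39, the metallothionein MT2A at 1.89 on 10 arrays, and FOSL2 was not called, at 0.17 on the feature used and 0.94 on its second feature. Its slide medians were 1.73, 1.77 and 1.68, and the adjusted p with slide as a block was 0.00136. The 3 measured members of the endothelial list, VCAM1, ICAM1 and ANGPT1 (1.47), were also higher in fetal. They were too few for the list test, VCAM1 and ICAM1 are induced by inflammatory signals in several cell types, and ANGPT1 encodes a ligand that acts on endothelium and is made mainly by other cells.

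The list of fatty acid uptake and oxidation genes leaned to adult heart RNA, with an adjusted p of 0.00331 with the preset correlation and adjusted p = 0.142 with an estimated correlation. Of 6 genes, 4 were called, among them CPT2 of the mitochondrial carnitine shuttle at -1.52 ± 0.0063 (SE, n = 18 arrays), ECH1 at -1.24 and ACOT8 at -1.08, while CPT1B, at -0.33, was not called. The slide medians were -1.02, -1.12 and -1.08, with an adjusted p of 0.00545 with slide as a block. ACOT8 was at -0.78 on the arrays with fetal RNA in Cy5 alone, short of the 2-fold limit. Of 20 genes of the respiratory chain and citrate cycle, COX11, an assembly factor of cytochrome oxidase, was called higher in adult (-1.14; -0.93 on the arrays with fetal RNA in Cy3 alone). The other 19 were not called, COX4I1 being at -0.02, and the list's adjusted p was 0.0913. Both fat cell markers measured, ADIPOQ and CIDEA, were higher in adult.

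The contractile genes went both ways. Of 11 genes, 3 were higher in adult, MYH2, MYOM3 and NEB, the giant thin-filament protein nebulin (-2.13), and 2 in fetal, TNNI2, the fast skeletal troponin I (2.35), and CSRP2 (1.61). ACTA2 was at 0.10, and the list did not pass (adjusted p = 0.614). MYH6, the alpha myosin heavy chain of heart muscle, was measured on 9 arrays with fetal RNA in Cy5 and on none of the swapped arrays, and was not tested. Its mean there was -0.94. Other heart genes chosen beforehand, such as NPPA and MYH7, were not analysed here. Of 13 ion channel and calcium handling genes, 3 were higher in adult, SLN, the calcium-binding S100A1 (-1.95) and CACNA2D3 (-1.24), and 1 was higher in fetal, the potassium channel gene KCNJ2 (1.08). TRPV2 was at -0.04, and the adjusted p was 0.245.

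The list of ribosomal proteins and translation factors leaned to fetal heart RNA, with an adjusted p of 0.0295 with the preset correlation and adjusted p = 0.47 with an estimated correlation. Of 12 genes 5 were called, all of them ribosomal proteins higher in fetal, among them RPS3A (1.97, n = 13 arrays), RPL6 (1.80) and RPS10 (1.51), while the initiation factor EIF2B1 was at 0.01. RPL21 was not called on the feature used (0.87), and its 4 features, from 0.87 to 1.04, differed in call. The slide medians were 0.81, 0.83 and 0.86, and the adjusted p with slide as a block was 0.0197. Of 9 cell cycle and replication genes, 5 were higher in fetal, including the mitotic kinesin KIF20A (2.11 ± 0.058, SE, n = 18 arrays), thymidine kinase TK1 (2.10) and the kinase CDC7 (1.93), and BRCA1 was at -0.05. This list did not pass (cameraPR, adjusted p = 0.54), though its median of 1.11 (1.03, 1.12 and 0.943 on slides 1, 2 and 3) exceeded the 0.846 of the ribosomal list. The list test compares the moderated t, in which a ratio counts less where it varies more between arrays. This t was 36.6 for KIF20A and 159.7 for RPL6, so the tests do not rank the lists by the size of their shift.

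Developmental regulators and signalling genes passed no list test. Of 11 cardiac and developmental transcription factors, NR2F1 (2.05) and HOXB5 (1.96) were higher in fetal, DLX1 was at -0.01, and the adjusted p was 0.7. Of 16 genes on the list of Wnt, Notch, Hedgehog, TGF-beta and BMP signalling, 7 were higher in fetal, among them FSTL1 (2.30) and the Wnt receptor FZD5 (1.59), and 1 in adult, the Notch ligand JAG2 (-1.09). The 7 include FGF13 (2.89), an intracellular FGF homologous factor that, like FGF12 (-0.49, not called), belongs to none of these pathways. SMAD2 was at -0.02, and the adjusted p was 0.245.

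Immune and blood genes differed in both directions. Of 6 leukocyte genes, S100A9, a neutrophil and monocyte protein, was higher in fetal (1.39 ± 0.0076, SE, n = 18 arrays) and the MHC class II gene HLA-DRB3 higher in adult (-1.38), with CD1A at -0.05 and an adjusted p of 0.976 for the list. The list's median was negative (-0.11), while its test leaned to fetal. Of 7 interferon and MHC class I genes, 4 were higher in adult, led by IFI44 (-1.65) and IFI27 (-1.36), and 1, IRF4, in fetal (1.51 ± 0.12), with HLA-F at -0.37 and an adjusted p of 0.245. Of 3 erythroid genes, HBM and the embryonic globin gene HBZ (1.38) were higher in fetal. None of 3 smooth muscle genes was called. Of 7 nerve genes, CHGB was higher in adult, and STMN2 (1.02), higher in fetal, fell under the 2-fold limit in 7 alternatives, among them the fit without replicate 11 of the fetal Cy5 arrays (0.99). GRIN2B was at -0.03, and the adjusted p was 0.614. Of 5 genes on the list of liver and yolk sac, CYP26B1, which degrades retinoic acid, was higher in fetal (1.95). It came onto the list by the spelling of its symbol. ITIH5 (-1.47) and the haptoglobin gene HP (-1.08) were higher in adult, and CYP2U1 was at 0.02, with an adjusted p of 0.643 for the list. HP was at -0.94 with fetal RNA in Cy3 alone.

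The lists of proteasome and ubiquitin, of chromatin, and of splicing and RNA processing genes held called genes in either direction, and none passed the list test. Among 11 proteasome and ubiquitin genes, USP36 (1.18) was higher in fetal, UBE2D4 (-1.28) and FBXW4 (-1.08; -0.93 with fetal RNA in Cy5 alone) were higher in adult, and FBXW9 was within 0.01 of 0, with an adjusted p of 0.404. Among 12 chromatin genes, BAZ1A (1.52) and SMARCAD1 (1.23) were higher in fetal, CBX7, a Polycomb protein (-1.52), and JMJD8 (-1.06) were higher in adult, and HMGN4 was at -0.01, with an adjusted p of 0.729. The median of this list was 0.01 and its mean 0.14, while its test leaned to adult. Among 14 genes on the list of splicing and RNA processing, RBM39 (1.38) and DDX10 (1.14) were higher in fetal. DDX28 (-1.26), the muscle and brain splicing factor RBFOX1 (-1.25) and RBM3 (-1.13) were higher in adult. DDX51 was at -0.06, with an adjusted p of 0.862 for the list. The glycolysis list, with GAPDH (0.19), and the list of natriuretic and endocrine genes, with EDN1 (0.87), had 1 member each, and neither was called. For each of the 24 lists, the counts adjusted over the list alone equalled those over all genes tested.

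**Figure D3:**
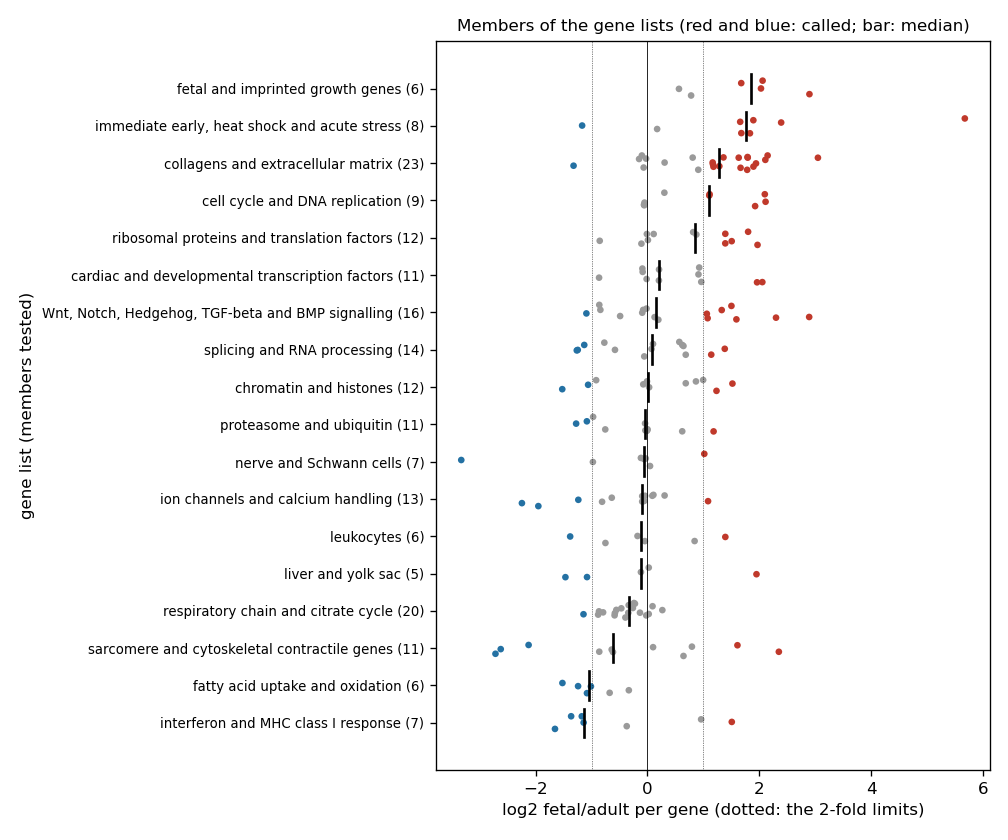
Log2 fetal/adult ratio (horizontal axis) of each member of the 18 gene lists with at least 5 members tested (vertical axis, number tested in brackets), with called members in red and blue, others in grey, and a bar at the median. The medians run from 1.85 in the fetal and imprinted growth genes to -1.14 in the interferon and MHC class I genes, of which the first passed the list test and the second did not.

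The self-self arrays gave the background of these ratios, after 155 unnamed features had been left out because their self-self ratio was low, and 31 because they were mostly at exactly 0. This choice lowers that background, so the values with these features kept, and over the features with a gene symbol, which were not chosen by their ratio, are given beside it. The SD of the log2 ratios over features was 0.184 ± 0.061 (SD, n = 6) on self-self arrays and 1.01 ± 0.030 (n = 18) on fetal against adult arrays, a difference larger than the spread between arrays by an exact permutation test over 134596 splits (2-sided p = 7.43e-06, the smallest they can give). On slides 1, 2 and 3 the self-self means were 0.196, 0.174 and 0.183, against 0.991, 1.04 and 0.992. Features at 2-fold or more made up 0.133% of those on a self-self array and 30.5% of those on a fetal against adult array. With the features kept, the mean SD was 1.44 ± 0.28 (SD, n = 6) and 1.84 ± 0.18 (n = 18; 2-sided exact permutation p = 0.000238), and the shares at 2-fold or more were 8.79% and 36%. Over the 1197 features with a symbol the mean SD was 0.183 and 1.01, and the shares were 0.0571% and 31.1%. No feature of 1575 was called on the self-self arrays by limma, where 94 passed the adjusted p alone and 530 an unadjusted p below 0.05, and 95% of the mean ratios were within 0.27 of 0. With the features kept, 155 were called and 331 passed the adjusted p, and over the 1118 features with a symbol that were tested 0 were called, 35 passed the adjusted p and 365 an unadjusted p below 0.05. The 94 fell to 0 with slide as a block, to 1 without each adult array in turn, and to 3, 56 and 2 without fetal replicates 1, 2 and 3. The dye term of the swapped arrays called no feature either, with 1074 of 1639 past the adjusted p alone and 1107 past an unadjusted p below 0.05, and it correlated with the self-self means across 1569 features (r = 0.842, rho = 0.850).

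**Figure D4:**
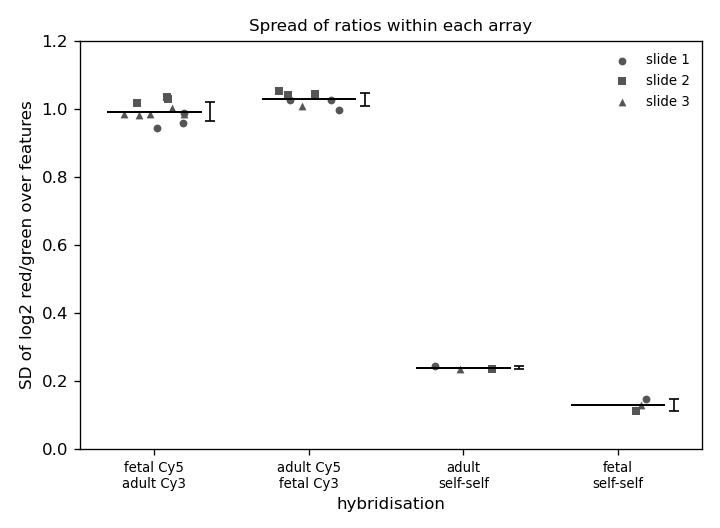
SD over features of the log2 red/green ratio (vertical axis) of each array by hybridisation (horizontal axis), without the 186 control-like features, with symbols for the 3 slides, a line at the mean and error bars of 1 SD. The fetal against adult arrays lie near 1, and the adult self-self arrays (mean 0.239) lie above the fetal ones (0.130).

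The ratios of the self-self arrays depended on the RNA. In adult self-self arrays IGF2BP1 was at -0.94 and the epoxide hydrolase gene EPHX1 at 0.74, against -0.13 and 0.03 in fetal self-self arrays. These 2 genes were chosen after their values were seen. The difference between fetal and adult self-self ratios passed limma's adjusted p at 764 of 1575 features (614 with slide as a block), of which 1, an unnamed feature, reached 2-fold, at 1.24. With 3 arrays against 3, no permutation of the arrays can give a p below 0.1.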

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

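The tests on the self-self ratios below, apart from the counts over other splits of the arrays, were chosen after the result was seen.

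Fetal and adult RNA differed in their self-self ratios, the same contrast of dyes in different RNAs, at 764 features past limma's adjusted p. The largest other count among the 10 splits of the 6 arrays into 3 and 3 was 1, and 1 split, the real one, gave 764, but 10 splits are too few for a share under 0.05. A dye bias of the features shared by both RNAs is argued against as the whole cause, also one that differs in strength between them, because the adult and fetal self-self means correlated across features with r = 0.17, and single arrays with r of 0.0208 to 0.284 between the RNAs against 0.384 or more within 1 RNA. The dye term of the swapped arrays followed the mean of both RNAs' self-self ratios with r = 0.843, which any cause that recurs from array to array would give, so it does not tell such causes apart. Labelled targets that differ between the channels and a dye bias that depends on abundance stay open, and a biological difference between the RNAs cancels in a self-self ratio unless it acts through such a bias.

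For the comparison of fetal with adult RNA, 1 of 100 splits of the 18 arrays, the real one, called as many as 505 features, and the highest other split called 181. The calls thus follow the dye orientation of the arrays. Swapped arrays correlated with r from -0.962 to -0.925, so a split that mixes orientations cancels the ratios and calls fewer features. The count therefore adds nothing on whether the RNAs or their preparations differ.

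Among the 7 arrays with fetal RNA in Cy3, 87 values were examined for an array far from the others, and 9 were found, where chance gives about 1 in 20. The distance is the gap to the nearest array as a share of the range. In COX11, IGF2 and EIF2B1 it was 1, where the array differed from identical others by 1 rounding step of 0.033. It was 0.618 for MMP9, 0.667 for FSTL1 and 0.667 for CBX7, with gaps of few such steps. The wider gaps were in FBXW9, where replicate 7 was at -0.60 against -0.13 to -0.01 on the others (0.79), in DLX1, where replicate 6 was at 0.56 against -0.23 to 0 (0.708), and in CXCL6, where replicate 2 was at 3.85 against 3.29 to 3.52 (0.588).

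Some features had too few values in 1 orientation for the test, yet exceeded 2-fold on every array that measured them and exceeded their self-self ratios. The 12 with a gene symbol are given here as mean log2 fetal/adult, without a test. RPS18, AZIN1, ZKSCAN1, TF and PTGDS had values in 1 orientation alone, so the dye swap does not check them. Those higher in fetal had values only with fetal RNA in Cy3, and those higher in adult only with it in Cy5. Their direction therefore goes with green over red. Their self-self ratios were at most 0.332 in size. The selection required fetal/adult ratios beyond the self-self ratios, so these do not decide on a dye bias. The features with values in both orientations kept their direction, with as few as 1 array in an orientation. The selection required this, so it is no separate evidence on dye bias. Higher in fetal were RPS18 (2.19, 5 arrays), MARCKS (2.01, 5 arrays), HMGB2 (1.66, 6 arrays), AZIN1 (1.65), ZKSCAN1 (1.40), NBPF1 (1.25), the chemokine receptor gene CXCR4 (1.23, 9 arrays) and COL27A1 (1.14, 4 arrays). Higher in adult were the transferrin gene TF (-2.73, 11 arrays), SYNPO (-2.37), the erythroid ankyrin gene ANK1 (-2.08, 5 arrays) and PTGDS (-1.54, 11 arrays). Tested second features of MARCKS and HMGB2 were at 1.67, which was called, and just under 2-fold, which was not. Of 186 control-like features, 1 was called between the RNAs and 157 passed the adjusted p alone.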

How the results depend on the processing

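Alternatives on control-like features, on features with a gene symbol and on exact zeros were chosen after seeing the data. The 505 calls between fetal and adult RNA stayed within 1.5 times under all alternatives but the lower fold limit. At 1.5-fold 821 features were called (475 higher in fetal, 346 in adult), and treat against 1.5-fold called 806 (467 and 339, and 806 past its adjusted p), by the construction of these settings. Leaving out single arrays gave 499 to 509 calls (301 to 307 higher in fetal, 196 to 202 in adult) and 1306 to 1347 features past the adjusted p alone. With 1 dye-balanced value per slide 502 were called, and with the control-like features kept 506. Of 3582 values of 84 named features under the alternatives, 3571 kept their side of the threshold. The other 11, of 5 genes (STMN2, ACOT8, FBXW4, COX11 and HP), fell under the 2-fold limit. Among features called in either fit 0 values reversed. A change of sign in an uncalled feature was not counted as a reversal. ACTA2, not called, was at 0.44 with fetal RNA in Cy5 alone and at -0.24 with fetal RNA in Cy3 alone.

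The dye term of the swapped arrays called 1 feature at 1.5-fold, and leaving out single arrays gave 0 calls and 1015 to 1071 past the adjusted p. On the self-self arrays 2 features were called at 1.5-fold and 155 with the control-like features kept, all of them features left out for a low self-self ratio. The 94 features past the adjusted p became 331 with control-like features kept, 35 over features with a symbol, 0 with slide as a block and 1 to 56 without single arrays: 1 without each adult array in turn, and 3, 56 and 2 without fetal replicates 1, 2 and 3. The cause was not tested. The single self-self feature that differed 2-fold between the RNAs became 20 at 1.5-fold, 9 with control-like features kept and 0 over features with a symbol (it has none; 590 passed the adjusted p), and was 1 without each array, with 602 to 732 features past the adjusted p.

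Of the gene lists 5 passed, against 2 with an estimated correlation and 18 with fry, which asks whether a list moves, on balance, one way and not whether it differs from other genes, and which was run on the genes with values on all 18 arrays alone, so that the test and the genes changed together. The list of splicing and RNA processing leaned to fetal in the list test and to adult under fry (adjusted p = 2.45e-12), which used 7 of its 14 genes. Which of the 2 changes, test or genes, turned the lean was not tested. The mean SD of fetal against adult arrays was 0.961 over features with values on all 24 arrays, where blank features are left out. With control-like features kept, the mean SD was 1.44 on self-self and 1.84 on fetal against adult arrays, and the mean share of features at 2-fold or more 8.79% and 36%, since the features left out for a low ratio lie far past 2-fold. Centring leaves an SD unchanged and is no test of it. By replicate number no paired analysis was possible because the numbers only follow the order of the samples. By slide it was: each slide holds 1 adult and 1 fetal self-self array, and with slide as a block 614 features passed the adjusted p of their difference, against 764 without it. What signal over background limits was not known without intensities.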

Other observations

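The tests of the kidney and stress genes below were chosen after the values were seen.

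Several genes known from kidney epithelium were among the largest ratios in favour of the fetal heart RNA. A list of 92 kidney genes was then written, of which 10 were measured and 9 called higher in fetal (median log2 ratio 2.23), but 7 of the 10 had been seen high before, so this count and median carry the choice and no enrichment was tested. The 7 were SPP1 (4.43), CDH16 (3.75), HSD11B2 (2.71), EMX2 (2.49), KNG1 (2.33), WFDC2 (2.13) and FXYD2 (2.13). Of the 3 that had not, ENPEP (1.53) and ELF3 (1.41) were called and MME (0.05) was not. None of the 10 is in another list used here, and how far heart itself expresses them was not measured.

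A dye or target bias of the size seen in the self-self arrays does not account for the kidney genes. The largest self-self mean of either RNA among the 9 was 0.487, against a smallest fetal/adult log2 ratio of 1.41. A bias that belongs to 1 RNA preparation is in both channels of a self-self array and cancels, so it is not covered. Kidney tissue in the fetal RNA is a candidate explanation, but 2 of 3 unseen genes leaves it open: MME, a brush border gene, did not follow, and the most abundant kidney transcripts of the list, such as UMOD, were not analysed here. The difference in age between the hearts, and any other tissue that expresses these genes, stay open and untested.

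The stress genes higher in fetal RNA (CXCL8, ATF3, MT2A, MYC at 1.83, EGR3 at 1.68 and EGR1 at 1.66) stood beside NFKBIA, ICAM1, VCAM1 and CXCL6, also higher in fetal. A dye or target bias of the size seen in the self-self arrays is argued against here too, with the same limit. The largest self-self mean among the 6 was 0.565 in size (MYC in adult RNA), against a smallest ratio of 1.66. Handling of the tissue before RNA isolation, inflammatory cells and age may each raise such genes and stay open. The MHC class II genes (HLA-DRA at -0.75, HLA-DRB3 at -1.38, beside S100A9 at 1.39) were not used as a test of leukocyte RNA. Their level in adult heart can hide a small share of leukocytes.

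Among the untested features, 21 without a gene exceeded 2-fold on every array that measured them and exceeded their self-self ratios: 11 were higher in fetal (means from 1.37 to 3.21) and 10 in adult (means from -2.62 to -2.15). Of the 11, 10 had values only with fetal RNA in Cy3, and of the 10, 9 only with fetal RNA in Cy5, so their direction goes with green over red. Their self-self ratios were at most 0.332 in size, on 1 to 5 self-self arrays. The selection required fetal/adult ratios beyond the self-self ratios, so these do not decide on a dye bias. Most of these features also have no swapped array to check it.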
